A study of Sander lucioperca with 15 samples.

How the data were processed

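Eggs were measured from 15 pikeperch females, 8 of a domesticated broodstock and 7 caught in the wild, with 1 array per female. Per the labels' protocols, about 50 mg of eggs of each female were frozen after collection, total RNA with an integrity number above 8 was kept, and 150 ng of it was amplified and labelled with Cy3 for a 1-colour Agilent array. The array carries 61537 spots of 36348 custom probes and 1439 control spots. Of the custom probes, 25189 were spotted more than once, and the probes had 35343 distinct sequences.

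The scanner values are spot intensities that the authors extracted with Agilent Feature Extraction, version 10.7.1.1 per the submitters' processing notes and version 10.7.3.1 per the file headers. Per the file headers, the processed intensity of a spot had its background subtracted and was corrected for spatial and multiplicative trends, weak spots received a surrogate value, and nothing was scaled between arrays. The flags for spots well above background, for outliers and for saturation, whose unit is a value of 0 or 1, were also set by that program, per the file headers. The authors' deposited value table is on the log2 scale. Set against the scanner values, it equalled the mean log2 processed intensity of each probe plus 1 constant per array, within 0.05 for 100% of the probes, and the median of each of its 15 columns was 3.59. Its scale and centring were settled by this comparison, and it holds levels, so it has no direction of its own.

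For the comparisons, control spots and outlier spots (2 to 19 per array) were left out, the log2 processed intensity was averaged over the spots of a probe, and the 75th percentile of each array was subtracted. Probes well above background on at least 7 of the 15 arrays were tested, which left 18046 probes (49.6%). Domesticated and wild eggs were compared with lmFit and eBayes of limma 3.58.1 in R 4.3.3, with p-values adjusted by the Benjamini-Hochberg method and called below 0.05. No spot was saturated. Where a probe was not well above background on any array of a group, its difference is given as a lower bound on the fold, from the mean of the brighter group against, on each array of the dimmer group, the higher of the probe's own value and the lowest signal among probes well above background. Single measures per array were compared with a two-sided exact permutation test over all 6435 splits of the 15 arrays. Files were read with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, plots were drawn with matplotlib 3.10.9, and probe sequences were aligned to each other with BLAST 2.17.0 (word size 11, E-value 0.001).

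The limma step was tested on simulated data for 18035 probes with the spread of the real arrays and 200 changed probes. It recovered 83 of 100 probes changed by 1 and 95 of 100 changed by 2 on the log2 scale, and 14 of its 192 calls fell on unchanged probes. The number of arrays limits the precision. Each array came from a different female, but the labels do not say how the females are related, so the p-values measure the spread between these females.

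The groups, the test, the filter, the alternative settings and the rule for named probes (the 15 largest changes in each direction) were chosen before the data were examined. The alternatives were normexp background correction with an offset of 50 (outlier spots included), quantile and median normalization, the authors' value table, no filter on dim probes and a stricter one, eBayes with trend and robust set, array weights, slide, array row and female number as blocks, and each array left out. Slide and scan coincided, since each of the 4 slides was scanned once, and every slide held both groups. The files name probes only by an identifier, a shortened contig name and a sequence, and the reference table of gene names could not be joined to these. The gene lists and the markers of other cell types (follicle, blood, immune, connective, endothelial and liver cells) fixed beforehand were therefore void, and no list was tested. In their place, probes were grouped after the files were seen by the tissue named in their contig. At most 2 probe identifiers per direction are printed.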

Results

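Pikeperch (Sander lucioperca) is a freshwater percid fish that is being brought into aquaculture. The series asked how the transcriptome of eggs of high quality differs between females of a domesticated population and wild females. The 8 domesticated females had been kept for 6 years in a recirculating system on compound feed and had spawned 3 times before. The 7 wild females were netted during the spawning season. Ovulation was induced in both groups with 250 IU per kg of human chorionic gonadotropin at 12 °C. Population, diet and rearing differed together between the groups.

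Each array detected between 17091 and 18893 probes well above background. The mean was 18101 ± 708 (SD, n = 8) in domesticated and 17669 ± 394 (SD, n = 7) in wild eggs, a difference within the spread between females (two-sided exact permutation test, p = 0.176, adjusted over 5 array measures p = 0.440). The 75th percentile of the log2 signal was 7.48 ± 0.12 (SD, n = 8) in domesticated and 7.29 ± 0.13 (SD, n = 7) in wild eggs (two-sided exact permutation p = 0.0145, adjusted p = 0.0723). It was subtracted from each array before the groups were compared.

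The array was built from contigs of 7 sources (eggs, testis, stomach, liver, kidney, muscle and larvae), with a few more from oocytes before ovulation that were left out here. Eggs gave signal for probes of each source. Of 818 probes from egg contigs, 652 (79.7%, 95% exact Clopper-Pearson interval 76.8 to 82.4%) were well above background on at least 7 arrays. The share was 54.9% of 10454 probes from testis, 50.7% of 3404 from stomach, 49.5% of 2129 from liver, 48.5% of 6475 from kidney and 46.1% of 7023 from muscle contigs. It was smallest for larval contigs, with 41.2% of 6039 probes.

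Domesticated and wild eggs differed in the signal of many probes, in which expression and sequence were not separated. Of 18046 probes tested, 4027 (22.3%) changed at an adjusted p below 0.05 in limma, of which 1881 were higher and 2146 lower in domesticated eggs. The changed probes represented 3870 distinct sequences. Most changes were small, with a median size of 0.57 on the log2 scale, and 922 probes changed at least 2-fold, 544 of them higher and 378 lower in domesticated eggs. With the normexp background correction, 283 probes changed at least 2-fold. The total fell to 1329 when the 75th percentile signal of each array was added to the model as a covariate, an alternative chosen after the data were seen. The count was 3870 with slide as a block. Within single slides, limma called 358 probes on slide 1, 63 on slide 2 and 47 on slide 3, each with 2 arrays per group. Slide 4 held 2 domesticated and 1 wild array, which left 1 residual degree of freedom and took the lone wild array to vary like the others, so its 0 calls (1677 probes at an unadjusted p below 0.05) say nothing for or against a difference. Of the probes called from the other 3 slides, between 90.9 and 96.2% had the same sign on the slide that was left out, against 69.3 to 75.8% of all tested probes.

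**Figure D1:**
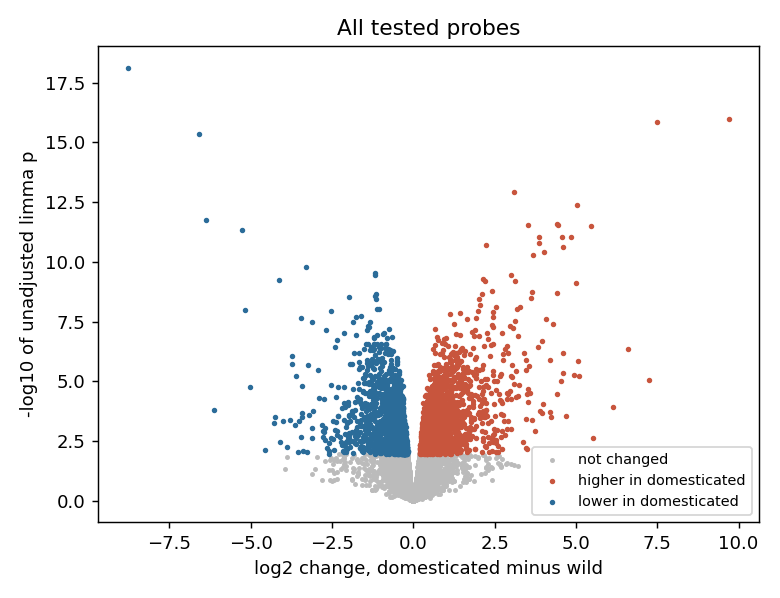
Each point is 1 of the 18046 tested probes, with the log2 change (domesticated minus wild) on the horizontal axis and the negative log10 of the unadjusted limma p on the vertical axis. The 1881 probes higher and the 2146 probes lower in domesticated eggs are coloured, and the sizes at the far ends rest on values below background in one group.

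Some probes were well above background in at least 7 females of one group and in none of the other. This held for 56 changed probes that were not well above background on any wild array and for 11 that were not on any domesticated array. These counts are not comparable, because the filter of 7 arrays admitted the former with 7 of 8 domesticated females and the latter only with all 7 wild females. Well above background on every array of one group and on none of the other were 27 probes for domesticated and 11 for wild eggs. In 852 probes the values of the groups did not overlap, against 5.61 probes (0.0311%) that chance gives. Measured differences of at least 8-fold were seen for 106 changed probes, 71 higher and 35 lower in domesticated eggs. Of these, the groups overlapped in 45 and did not in 61, values below background included. As 31 of the 106 were not well above background on any array of one group, the filter also bears on the split by direction. With every value raised to the lowest signal well above background on its array, 57 of the 106 still differed at least 8-fold, and with normexp 8 did.

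Probes were ranked by the measured log2 change, which for the following 4 rests on values below background in one group. Each size is therefore given as a lower bound under the background subtraction used, and the order of these probes is not established. The probe with the largest measured increase was CUST_19314_PI439957682, from a muscle contig, with the sequence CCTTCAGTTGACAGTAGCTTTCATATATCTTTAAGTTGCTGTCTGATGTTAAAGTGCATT. Its normalized log2 signal was 3.67 ± 0.62 (SD, n = 8) in domesticated eggs, and it was well above background on none of the 7 wild arrays, so it was at least 205-fold higher in domesticated eggs (limma, adjusted p = 8.3e-13). The probe CUST_15229_PI439957682, from a liver contig (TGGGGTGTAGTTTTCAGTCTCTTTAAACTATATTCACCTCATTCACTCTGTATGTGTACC), was at least 41.7-fold higher (limma, adjusted p = 8.3e-13), with a signal of 1.37 ± 0.53 (SD, n = 8) in domesticated eggs and none well above background in the 7 wild ones. The probe ranked next had a larger bound, at least 52.7-fold. The files do not pair the probes with genes.

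The largest measured decrease was that of CUST_13225_PI439957682, from a larval contig, with the sequence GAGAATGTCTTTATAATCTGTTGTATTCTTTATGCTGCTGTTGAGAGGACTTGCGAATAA. Its normalized log2 signal was 2.42 ± 0.34 (SD, n = 7) in wild eggs, and it was not well above background on any of the 8 domesticated arrays, which puts it at least 95.1-fold lower in domesticated eggs (limma, adjusted p = 1.3e-14). The probe CUST_9434_PI439957682, also from a larval contig (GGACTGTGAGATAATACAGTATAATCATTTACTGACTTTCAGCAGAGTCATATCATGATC), was at least 29.8-fold lower (limma, adjusted p = 1.9e-12), with 0.75 ± 0.12 (SD, n = 7) in wild eggs. The adjusted p-values test the measured log2 changes and not the bounds. With normexp, whose offset compresses low signals, the log2 changes of the 4 probes were 5.19, 2.90, -4.16 and -2.56, in the order given. These are smaller in size than the bounds, which hold only for the background subtraction used. With slide as a block, the lower bounds of these probes were 199-fold, 41.6-fold, 94.7-fold and 29.6-fold, in the same order. All of them kept their direction within each of the 4 slides, where the bounds ran from 146 to 301-fold for CUST_19314_PI439957682, from 26.3 to 58.8-fold for CUST_15229_PI439957682, from 85.9 to 109-fold for CUST_13225_PI439957682 and from 25.0 to 33.4-fold for CUST_9434_PI439957682.

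**Figure D2:**
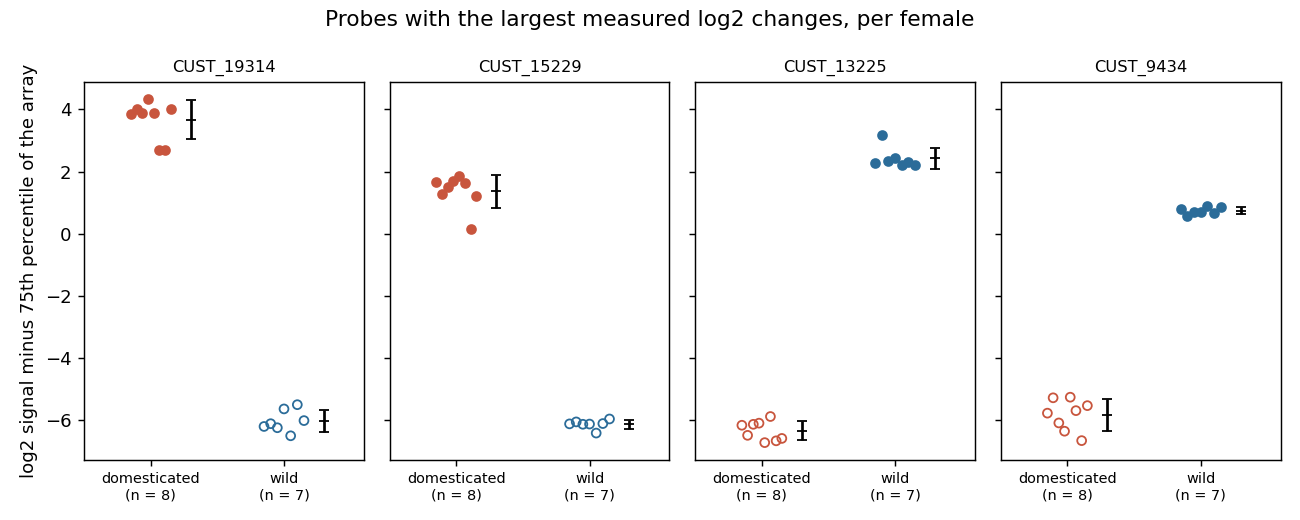
Each point is 1 female, with the log2 signal minus the 75th percentile of its array on the vertical axis, for the 2 probes with the largest measured increase and the 2 with the largest measured decrease in domesticated eggs. Open points were not well above background, and the bars give the mean and SD of 8 domesticated or 7 wild females. The groups do not overlap in any of the 4 panels.

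Among the 15 probes with the largest measured increases, 9 were not well above background on any wild array, with lower bounds from 7.72 to 205-fold. The other 6 were well above background on 1 to 5 wild arrays. Of the 15, 7 came from testis contigs and the groups did not overlap in 9. For the probe ranked 9, the gap of 0.12 on the log2 scale lay between values not well above background, which have no order. Among the 15 with the largest measured decreases, 5 were not well above background on any domesticated array, with lower bounds from 3.72 to 95.1-fold. The other 10 were well above background on 1 to 8 domesticated arrays. Of these 15, which held 14 distinct sequences, 3 came from testis contigs and the groups did not overlap in 7. Of both sets, 0 probes came from egg contigs. Among all 18046 tested probes, 5743 came from testis and 652 from egg contigs, so 0 among these few does not show a lack of egg contigs.

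Changes were spread over the contigs of all 7 sources. Of the 652 tested probes from egg contigs, 89 (13.7%) were higher and 67 (10.3%) lower in domesticated eggs, and 10.3% of all other probes were higher. The excess of higher probes missed the threshold (two-sided Fisher's exact test, p = 0.00740, adjusted over 14 comparisons p = 0.104). Fisher's test takes probes as independent, so its p-values do not measure the spread between females. The excess depended on the setting. It passed the threshold in some settings and took the opposite sign with the 75th percentile signal as a covariate. Testis contigs gave 600 higher and 714 lower probes, muscle contigs 344 and 352, kidney contigs 314 and 342, larval contigs 241 and 315 and stomach contigs 186 and 214, and liver contigs had 249 changed probes. No source passed in camera with the preset correlation of 0.01 (smallest adjusted p = 0.995) or with an estimated correlation (smallest adjusted p = 0.995). In fry, which asks whether the probes of a source move on balance one way, the smallest adjusted p was 0.0651. In its mixed form, which counts change either way, each of the 7 sources passed (fry, adjusted p from 6.8e-25 for kidney to 1.0e-14 for egg contigs). As 22.3% of all tested probes changed, sets of this size were likely to pass whatever their source. The mixed form therefore shows nothing particular to a source.

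The females of a group resembled each other more than those of the other group. Across 18035 probes, which are not independent replicates, Pearson's r averaged 0.975 over 28 pairs of domesticated females (0.967 to 0.986), 0.976 over 21 pairs of wild females (0.972 to 0.980) and 0.956 over 56 mixed pairs (0.95 to 0.963). The first principal component took 34.1% of the variance and separated the 8 domesticated from the 7 wild females. The distance of a female from the mean of its group was 0.177 ± 0.0111 (SD, n = 8) on the log2 scale in domesticated and 0.181 ± 0.0209 (SD, n = 7) in wild eggs, a difference within the spread between females (two-sided exact permutation test, p = 0.712).

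**Figure D3:**
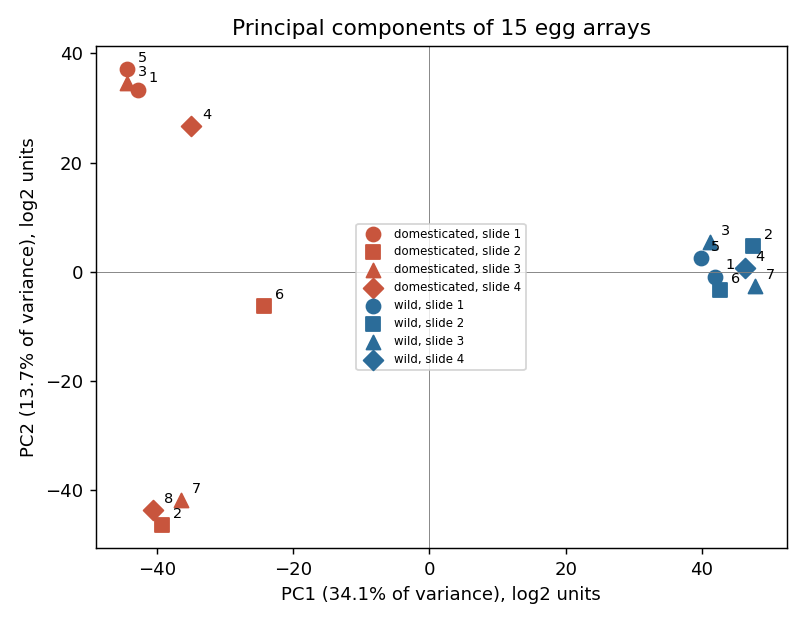
Each point is the array of 1 female, labelled with its number, with the first component (34.1% of the variance) on the horizontal and the second (13.7%) on the vertical axis, both in log2 units; colours give the group and shapes the slide. The 8 domesticated females lie on the negative side of the first component and the 7 wild females on the positive side, and the second component spreads the domesticated females from -46.5 to 37.2.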

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

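The tests of slide and of highly variable probes for the split of the domesticated females, of other splits for the number of changed probes, of overlapping probes and of signal floors were chosen after the result was seen. Slide as a block was planned, but what would count against slide was set after its result.

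The 4027 changed probes were set against 100 splits of the 15 arrays into 8 and 7. Only 1 gave as many calls, the labelled one with 4026 of the 18035 probes measured on all arrays. The highest of the others gave 23, which argues against a random division of these 15 females. The share of 1 in 100 is the smallest this test can give, and the other splits mixed the groups, which widens their spread. Chance in which families were sampled was not tested, as the labels do not say how the females are related. Slide alone is argued against, since 3870 probes were called with slide as a block. With the 75th percentile signal of the array as a covariate 1329 probes were called, while 50 random covariates with the same correlation with group (r = 0.63) left 1327 to 2923, with a median of 1892. The count met the bound set beforehand, to lie within that range, but only at its edge, as 1 random covariate left as few, so this was not taken to exclude array signal, which may account for part of the count. The 75th percentile averaged higher in domesticated than in wild arrays, although the groups overlapped and the difference missed the threshold after adjustment over array measures (exact permutation, adjusted p = 0.0723), and because it correlates with group, that part and the difference between domesticated and wild females, itself confounded with diet and rearing, cannot be told apart.

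The domesticated females fell into parts that the labels do not name. Of the 35 splits of the 8 females into 4 and 4, that of females 1, 3, 4 and 5 against 2, 6, 7 and 8 called 248 of 18035 probes and the next highest 3; of the 56 splits into 5 and 3, that of 2, 7 and 8 against the rest called 480 and the next highest 41. Female 6 stood apart from both parts, at -6.22 on the second component and with r of 0.969 to 0.974 with each other domesticated female, while the highest of the 35 splits of the 7 wild females into 4 and 3 called 9. Slide is argued against, because on 2 of the 4 slides the domesticated females lay on opposite sides of the second component, 76.4 and 70.3 apart, while all wild females spanned 8.86. Array signal and a few highly variable probes are also argued against, since the split into 4 and 4 called 157 probes with the 75th percentile as a covariate and 158 without the 5% most variable probes. Shared parentage may underlie such parts, but the labels give no families, and no biological explanation was tested.

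The 106 probes that differed at least 8-fold were followed up; the groups overlapped in 45 of them. With normexp, 99.1% (105 probes) kept call and direction, so the choice of this correction changed neither for nearly all of them. Normexp reworks spots of the same arrays, and the probes were picked for a large difference there, which makes such agreement likely. The share therefore does not exclude background handling for call and direction. The sign was the same within all 4 slides for 96.2% (102 probes). The probes were picked for a large difference on these same arrays, which favours such agreement, so the share does not decide on slide. Background handling also stays open for the size of the change. With values raised to the lowest signal well above background on each array, 53.8% (57 probes) still differed at least 8-fold. The median size fell from 3.73 to 1.46 on the log2 scale with normexp, whose offset compresses low signals. A sequence difference under 1 probe stays open. Examined were 27 pairings with a tested probe that aligned over 20 to 54 bases, mismatches allowed, covering 10 of the 106 probes. A pair with both probes among the 106 was counted from each side. Of the pairings, 55.6% (15) changed at least 2-fold in the same direction, between the bounds set for either outcome. The difference between domesticated and wild populations, in expression or in sequence, may lie behind the 106 probes and was not separated further.

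Over 9 measures in both groups (18 sets of females), 3 single values lay far from the others of their group, where chance gives about 1 in 20 groups. Domesticated female 7 was lowest for CUST_15229_PI439957682, at 0.17 against 1.21 for the next. Wild female 2 was highest for CUST_13225_PI439957682, at 3.18 against 2.43. Wild female 5 was lowest for CUST_15229_PI439957682 at -6.42 against -6.13, and both values were not well above background, where values have no order.

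Of 12 control probes for mammalian GAPDH and PGK1, which the comparisons left out, 6 lay above the highest value of the negative control on all 15 arrays, and 2 of them exceeded the negative control of the same array by over 3 on the log2 scale on all 15. The log2 signal averaged 9.03 for Mouse-GAPDH_5, 5.36 for Rat-GAPDH_3, 3.94 for Human-GAPDH_3, 3.24 for Rat-GAPDH_5, 2.29 for Rat-PGK1_5 and 1.92 for Mouse-PGK1_5, while the negative control averaged 1.18.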

How the results depend on the processing

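The covariate, the tissue groups, the subsets of females and the use of 1 probe per sequence were chosen after seeing the data. The number of changed probes stayed between 3152 and 4304 in the other settings, and between 3441 and 3923 when 1 array was left out. All calls shared with the first analysis kept their direction, and those shared ranged from 66.8% (no filter on dim probes) to 97.3% of it, and were 31.9% with the covariate. With the 75th percentile signal as a covariate, 1329 probes changed, 703 higher and 626 lower, and 587 at least 2-fold; part of this drop follows from the correlation of signal with group. Requiring 2-fold beside the adjusted p left 922. At least 2-fold changes numbered 283 with normexp, whose offset compresses low signals, and 449 among probes well above background on all arrays, a filter that leaves out probes dim in one group.

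The labels give both groups the same female numbers, which name different fish. With female number as a replicate block, 3156 probes changed. Same-numbered females correlated from -0.024 to 0.124 in their deviations, and 2 of the 7 domesticated females with a wild namesake correlated best with it, so the numbers do not pair the fish, although same-numbered females also shared a slide.

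The log2 odds of a higher call for egg contigs was 0.46 and rose to 0.58 with normexp (adjusted p = 0.0153), 1.02 with no filter on dim probes (adjusted p = 7.8e-06) and 0.61 on probes well above background on all arrays (adjusted p = 0.00829), all past the threshold. The value with no filter does not part change from detection. Of egg-contig probes 79.7% pass the filter, against 41.2 to 54.9% for the other sources, which therefore add a larger share of dim probes. Without single females the log2 odds ranged from 0.26 to 0.65 and passed without domesticated female 4 (0.65) and wild female 5 (0.48). It was -0.37 with the 75th percentile covariate (adjusted p = 0.517). Over all settings the adjusted p from Fisher's exact test ran from 7.8e-06 to 0.517. These p-values take probes of the same females as independent and do not measure the spread between females. The cause was not tested.

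The difference in spread between females, -0.0034, became 0.00053 with normexp and 0.0022 with quantile normalization, and ranged from -0.0099 to 0.0046 when 1 female was left out, with exact permutation p from 0.236 to 0.952. The cause was not tested.

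Of the 30 named probes none reversed, and 7 lost the call in 28 combinations of probe and setting. Gene lists and cell-type markers were not run, for want of gene names. Below background only bounds can be given.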

Other observations

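Tests of steps within groups and of subsets of females were chosen after the result was seen.

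Any 3 domesticated females sufficed to show a difference from the 7 wild ones: the 56 sets called 786 to 2742 probes, with a median of 1416. The 35 sets of 3 wild females against all domesticated called 1339 to 2304.

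Probes with a high signal in some females and a low signal in others of the same group were found in both groups. A step of at least 2 on the log2 scale between neighbouring females occurred in 291 probes among the 7 wild females and in 250 among the 8 domesticated. It set a single female apart in 182 of the wild and 92 of the domesticated probes. The most frequent partition of the domesticated females put 1, 3, 4, 5 and 6 against 2, 7 and 8 (32 probes), then 1, 3, 4 and 5 against 2, 6, 7 and 8 (31 probes). In the wild females it was female 4 against the rest (45 probes). Of the 291 probes with such a step in wild females, 58 also changed between the groups, and of the 250 in domesticated females, 68 did. Among all tested probes 22.3% changed, and a link between steps and the group difference was not tested. Steps were counted whether or not the lower values were well above background, and where they were not, the size of the step is not established. Expression and sequence were not separated in these probes.

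Probes with identical sequence gave nearly the same change: over 787 pairs of tested probes the log2 changes correlated at r = 0.986 across pairs, which are not independent replicates. It was 0.792 over 711 pairs that overlapped by identical bases and 0.617 over 2885 pairs with differences in the overlap. In these, 0 pairs changed by over 1 in opposite directions.

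One hypothesis was that the probes differing at least 8-fold belong to families of similar sequence more often. A similar probe, meaning any aligned probe of the same strand without full identity, existed for 16.0% of them (17 of 106) and 15% of the other tested probes. The odds ratio was 1.08 (two-sided Fisher's exact test, p = 0.785), so no excess was detected. Partial overlaps of identical bases also counted as similar. Families were therefore not parted from overlapping probes of the same transcript, and the test does not decide on families.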
